A study of Rattus norvegicus with 6 samples.

How the data were processed

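Total RNA from the renal cortex of 6 male Sprague-Dawley rats, bought at 5 weeks of age, was labelled with Cy3 and hybridised to 1-colour Agilent rat arrays, per the labels' protocols. The groups were water control (n = 3) and NDMA (n = 3), taken from the sample titles, and replicates were separate animals, per the series' design text. Spot intensities were extracted by the authors with Agilent Feature Extraction, version 10.7 per the submitters' processing notes and 10.7.1.1 per the file headers. The deposited processed intensity is the Cy3 signal of a spot after subtraction of background and removal of a spatial trend on its own array, with no scaling between arrays, per the file headers. The deposited median intensity and background intensity of each spot are unscaled pixel values. The authors' value table holds a linear ratio that matched each array's processed intensity divided by its own 75th percentile, with a largest log2 difference of 0.00174 over values above 0.1. Its scale and direction are therefore known and no centring of genes was found, and its columns had medians of 0.112, 0.110 and 0.114 for the controls and 0.115, 0.112 and 0.114 for NDMA. The array's own annotation names genome build rn4, which is not the build of the gene table used here, so no coordinates are given.

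Processed intensities were taken to log2 and reduced by each array's 75th percentile over the 61657 non-control probes, which ranged from 993 to 1053 on slide 1 and was 1310 and 1299 on slide 2. Spots flagged as outliers were set missing, which affected 18 values of the probes tested. Probes were kept if they were well above background on all 3 arrays of at least 1 group, which left 43118. Each gene was represented by its brightest probe over the 6 arrays. Gene names came from the RefSeq table of rat assembly GRCr8 by accession without version: 27348 of 29123 NM accessions matched, 27460 probes were named and 34197 kept the file's own name. Genes such as Mki67 and Top2a had no probe matched by name. A gene whose probes were not well above background on any array of a group has only a bound there: its fold is given as "at least", the brighter group's mean against the mean of, per array, the higher of the probe's own signal and the lowest signal well above background. These bounds hold for the processed signal and not for the normexp settings, whose offset shrinks the differences of dim probes. Among the 63 called named genes, 25 had more than 1 probe passing the filter, and in 24 of these all probes had the gene's direction.

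Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 4 residual and 2.36 prior degrees of freedom) with Benjamini-Hochberg adjustment over the 31915 features and a threshold of 0.05. Values are log2 differences, NDMA minus control, with the moderated standard error. An exact permutation test of 3 against 3 animals cannot go below p = 0.1 (two-sided), so none is given for single genes. The number of arrays limits the precision. Gene lists were tested with camera at its preset correlation of 0.01, adjusted over 33 lists with at least 5 measured genes, and again with the correlation estimated from the residuals, with fry, which tests whether the genes of a list move one way and does not compare them with other genes, and with camera on ranks. The lists hold 710 entries, of which 3 could not be resolved to a current symbol. A list's counts are given over all features tested and adjusted over the list alone. List members with a missing spot were left out of the list test.

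The test, the lists, the rule for named genes and all alternatives but the normexp settings and the test of named genes alone were fixed before the data were examined. The rule takes, in each direction, the 12 largest changes past the threshold among genes with a symbol whose groups do not overlap; in each list up to 4 members past the threshold by smallest p, or in lists past the list test the 3 with the smallest p; and 9 genes always (Mgmt, Cyp2e1, Cdkn1a, Mdm2, Havcr1, Lcn2, Mki67, Slc34a1 and Umod). It named 85 genes, of which 84 were measured and 63 passed, and a few of them are not given in the text. Other genes named under Results, such as Irf1, Mx1, Gzmb, Ccl7, Pcna, Kif11 and Hbb, are list members chosen after their values were seen, to show the members that did not pass or to complete a short count. Further genes named under Other observations were also chosen after their values were seen, and many of them are not list members.

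The fit was tested on simulated arrays with the means of the 31915 features and 200 changed genes. Each feature's spread was its own estimate on 4 degrees of freedom. Such estimates vary more between features than the true spreads, so the recovery need not hold for the real data. The fit recovered 8 of 67 genes changed 1.5-fold (11.9%), 39 of 67 changed 2-fold (58.2%) and 59 of 66 changed 4-fold (89.4%). It called 6 of 31715 unchanged genes. A raised list was called and 0 unchanged lists were. Simulated genes varied independently, so this cannot show how the list test behaves where members vary together. The estimated correlation was 0.73 for mitosis. Each of the other splits of the 6 animals, which mix the groups, called lists, from 3 to 13, against 15 for the real split.

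Slide was read from the file headers, and the 2 slides were scanned on different days. Slide 1 held 4 arrays, 3 of them controls, and slide 2 held 2 NDMA arrays, so slide was fitted as a fixed block, as a random block and by slide 1 alone. In the fit of slide 1 alone and in the fixed block the NDMA effect rests on NDMA animal 1, whose spread is assumed to be that of the other animals. A list p-value there would measure spread over genes and not between animals, so list medians are given for these fits and no list p-values. The alternatives covered the normalisation, background correction, probe filter, gene summary, slide, replicate number, each animal left out, variance model, threshold and list test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.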

Results

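Gene expression was measured in the renal cortex of 6 male Sprague-Dawley rats on 1-colour Agilent oligonucleotide arrays, with 1 array per animal. Water was given to 3 rats, and the other 3 received N-nitrosodimethylamine (NDMA), a nitrosamine that is oxidised in the body to a compound that methylates DNA, at 4 mg/kg/day for 4 weeks. On each array between 43016 and 46248 of the 61657 probes were well above background, and between 0 and 4 spots were saturated. The detection filter left 43118 probes for 31915 features, of which 12175 carried a RefSeq gene name. Pearson correlations across genes, which are not independent replicates, ran from 0.992 to 0.995 between arrays of 1 group and from 0.985 to 0.990 between groups. The 3 controls and NDMA animal 1 were hybridised on slide 1, and NDMA animals 2 and 3 on slide 2, which was scanned on another day. The first principal component held 44.8% of the variance. The controls lay between -39.8 and -32.0 on it, NDMA animal 1 at 25.9 and the slide 2 animals at 31.2 and 48.2.

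The comparison asked which transcripts of the renal cortex differed after 4 weeks of NDMA. Cxcl9, a chemokine that is induced by interferon gamma and attracts T cells, was 60.1-fold higher in NDMA-treated rats (log2 difference 5.91 ± 0.28 SE, n = 3 per group, adjusted p = 0.00244), with a log2 difference of 4.46 under normexp background correction. Cxcl10, a chemokine acting on the same receptor, was 13.1-fold higher (3.71 ± 0.15, adjusted p = 0.00175). Transcripts of interferon gamma itself, Ifng, were not well above background in any control and were at least 1.94-fold higher in NDMA-treated rats (2.76 ± 0.21 as fitted, 0.49 with normexp, adjusted p = 0.00582). Among genes with a symbol that passed without overlap of the groups, each read by its brightest probe, the largest fall was that of Gabbr2, a subunit of the GABA-B receptor, with a log2 difference of -1.95 ± 0.36 (3.87-fold, adjusted p = 0.0450, and 0.0505 with a trended and robust variance). The Gabbr2 call was kept in 1 of the 6 fits without 1 animal.

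Other genes with large rises included Gbp5, an interferon-induced GTPase (7.18-fold, 2.84 ± 0.21), and Pimreg, a gene of the mitotic phase of the cell cycle (6.90-fold, 2.79 ± 0.11, and 1.23 with normexp). Acod1, which makes itaconate in activated macrophages, was not well above background in the controls and was at least 4.81-fold higher after NDMA. The same held for Cma1, a mast cell chymase, at least 4.26-fold higher, and for Tlr10, Ffar4 and Ddias, which were at least 3.54-fold, 3.42-fold and 2.18-fold higher. With normexp the log2 differences of Acod1, Cma1, Tlr10, Ffar4 and Ddias were 1.05, 0.72, 0.66, 0.59 and 0.51, below these bounds, and the calls of Cma1 and Ddias were lost (adjusted p = 0.0902 and 0.0838). Mcpt1, a mast cell protease, was 13.8-fold higher (3.79 ± 0.71, adjusted p = 0.0495, and 0.0548 with quantile normalisation), with normalised log2 signals of -0.90, -3.48 and -1.08 in NDMA animals 1 to 3 and from -6.20 to -5.09 in the controls. Fcnb, a secreted lectin of the complement pathway, rose 6.67-fold (2.74 ± 0.34). For Mcpt1, Cma1 and Gbp5, which have close relatives in the genome, binding of related transcripts to the probes was not tested.

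Among the genes that fell, Nefm, a neurofilament subunit, had a log2 difference of -1.88 ± 0.27, and Cnnm1, Lamc3 and Crb1 had differences of -1.52 ± 0.27, -1.39 ± 0.25 and -1.23 ± 0.14. The other Lamc3 probe differed by -0.33 ± 0.13 (adjusted p over probes 0.255). With normexp Lamc3 was at -0.91 and Crb1 at -0.80. Crb1 alone of the genes named in this paragraph kept its call in each of the 6 fits without 1 animal. Dio1, the deiodinase that activates thyroid hormone, had -0.89 ± 0.16 (adjusted p = 0.0416, and 0.0638 with quantile normalisation), and Ltc4s, the enzyme that makes leukotriene C4, -0.96 ± 0.14 by its brightest probe and -2.44 ± 0.38 by another. The calcium channel gene Cacna1h and the calcium-binding protein gene Casq1 had differences of -1.02 ± 0.17 and -0.98 ± 0.17, and the glycosyltransferase gene Galnt16 one of -0.85 ± 0.14. A pair of olfactory receptor genes, Or8b54b and Or4p7, had differences of -1.20 ± 0.17 and -0.93 ± 0.11 at a low signal, and belong to a large family of similar sequences. With normexp and quantile normalisation these were -0.42 and -0.24, and the call of Or4p7 was lost (adjusted p = 0.143).

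Over all features, 957 differed between the groups at an adjusted p under 0.05, of which 805 were higher and 152 lower after NDMA (84.1% higher). Among them 485 had a RefSeq gene name, 427 higher and 58 lower. A change of at least 2-fold was found for 519 higher and 21 lower features. In 27.6% of the tested features the groups did not overlap, where chance gives 10%. With normexp background correction from the median signal, a setting chosen after the data were examined, the count was 1093, of which 732 were higher and 361 lower (67.0% higher).

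With the slide as a fixed block, 67 features passed, 59 higher and 8 lower, and 41 of them were among the 957; on slide 1 alone, where NDMA animal 1 stood against the 3 controls, 0 features passed in limma, with 3501 at an unadjusted p under 0.05. The count fell from 957 to 364, 520 and 505 without control 1, 2 and 3, and to 749, 458 and 367 without NDMA animal 1, 2 and 3.

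**Figure D1:**
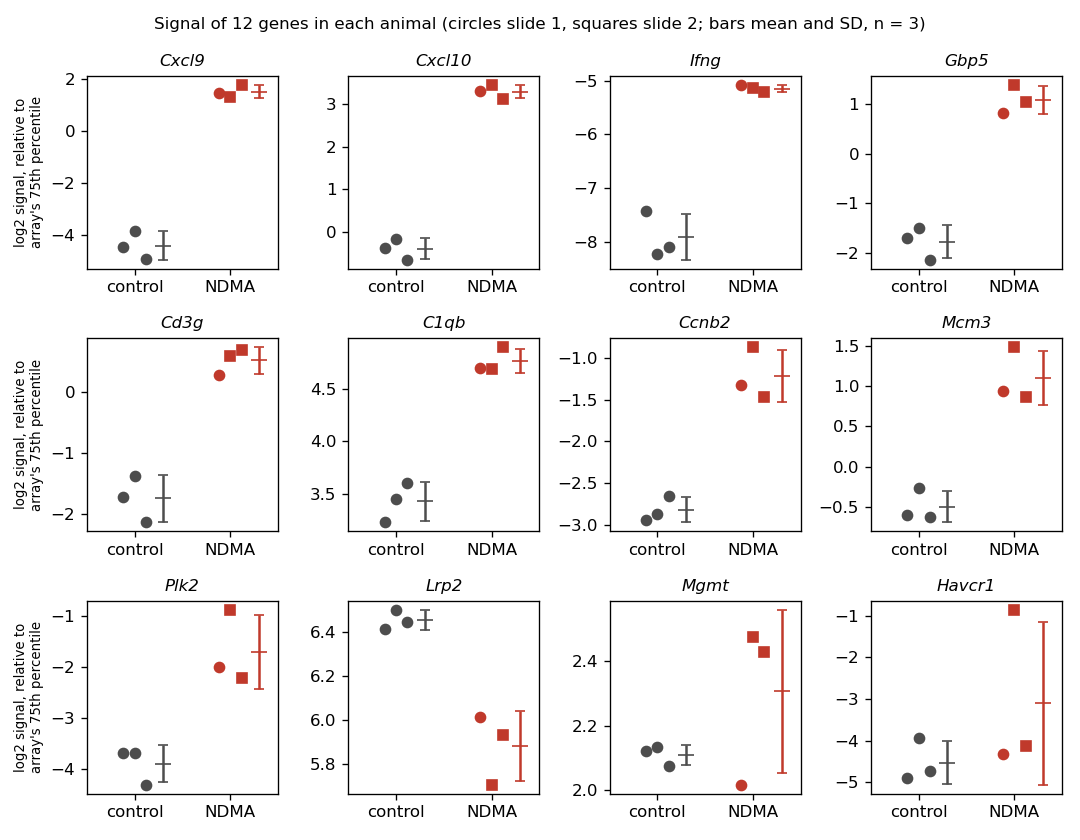
Normalised log2 signal of 12 genes in each of the 6 animals, with a separate vertical axis for each gene; grey points are controls, red points NDMA, circles slide 1 and squares slide 2, and the bars give the mean and SD of 3 animals. For Cxcl9 the 3 NDMA animals lie between 1.30 and 1.78 and the controls between -4.92 and -3.83, while for Havcr1 only NDMA animal 2, at -0.85, stands apart; the controls of Ifng were not well above background.

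Genes of macrophages, dendritic cells and T cells were higher in the cortex of NDMA-treated rats as lists, though not with an estimated correlation (adjusted p = 0.242). Of 22 measured macrophage and dendritic cell genes, 16 rose, 0 fell and 6 did not pass, with a median log2 difference of 1.13. They included Cd68, a lysosomal protein of macrophages (2.80-fold, 1.48 ± 0.14), C1qb, a complement component made by macrophages (2.51-fold, 1.33 ± 0.12), Ptprc, the pan-leukocyte marker CD45 (2.45-fold, 1.29 ± 0.12), and the lectin receptor gene Clec4a3 (2.22-fold, 1.15 ± 0.11). Of 19 T and NK cell genes, 10 rose and 0 fell, with a median of 1.20. The T cell receptor chains Cd3g (4.79-fold, 2.26 ± 0.21), Cd247 (3.89-fold, 1.96 ± 0.13) and Cd3d (2.44-fold, 1.29 ± 0.12) and the kinase Zap70 (2.29-fold, 1.20 ± 0.11) were among them. Members that did not pass included the granzymes and perforin, with log2 differences of 0.25 for Gzmb, -0.12 for Gzmm, -0.48 for Prf1, and also Klrd1 at -0.58 and Nkg7 at -0.10. Of 7 B and plasma cell genes 3 rose, namely Cd37 (0.85 ± 0.10), Fcrla (0.81 ± 0.12) and Blk, the last at least 1.71-fold, whereas the B cell receptor gene Cd79b had a difference of -0.08. The neutrophil and mast cell list did not pass (adjusted p = 0.0637). It passed with the median of each array (adjusted p = 0.0439), and its median was 0.25 on slide 1 alone, which rests on NDMA animal 1. Of its 8 members only Mcpt1 rose, and the neutrophil genes S100a8 and S100a9 had differences of 0.03 and -0.01.

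The macrophage list (adjusted p = 7.01e-23), the T and NK cell list (1.06e-11) and the B and plasma cell list (0.00271) passed the list test with camera's preset correlation, and none did with an estimated correlation (adjusted p = 0.242 for each). Adjusted over the list alone, 19, 14 and 4 members rose and 0, 2 and 0 fell. In NDMA animal 1, on the controls' slide, the mean over the members was 0.92, 1.06 and 0.72 above the control mean for the 3 lists. With the slide as a block, which rests on that animal, the list medians were 1.02, 1.07 and 0.70. The B and plasma cell list did not pass over probes well above background on all arrays (adjusted p = 0.0622, median 0.12).

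Interferon response genes moved unequally, and those that rose ran from Stat2 at 0.53 ± 0.08 to Cxcl9. Of 26 measured members 11 rose and 0 fell, with a median log2 difference of 0.56. Besides Cxcl9 and Cxcl10, the peptide transporter Tap1 rose 5.39-fold (2.43 ± 0.16), the immunoproteasome subunit Psmb9 5.39-fold (2.43 ± 0.12) and the GTPase Gbp2 5.92-fold (2.57 ± 0.18). The transcription factor Irf1 had a difference of 2.11 (adjusted p = 0.00607). The antiviral genes Mx1, Mx2, Oas1a, Ifit3 and Irf7 had differences of 0.13, -0.38, -0.32, 0.19 and -0.46, and none of them passed. Isg15 and Rsad2 were higher, at 0.62 ± 0.15 and 0.59 ± 0.15, and did not pass either. Of 24 cytokine and chemokine genes 7 rose and 0 fell, with a median of 0.66. These were the chemokines Cxcl11 (4.07-fold, 2.02 ± 0.16) and Ccl7, the pentraxin Ptx3 (5.74-fold, 2.52 ± 0.20), the interleukin Il18 (1.90-fold, 0.92 ± 0.11), the adhesion molecule Icam1 (1.59-fold, 0.67 ± 0.10) and the complement genes C4a and Cfb. With normexp Ptx3 differed by 1.28. Ccl5 and Il1b did not pass, with differences of -0.29 and 1.22.

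Both lists passed with the preset correlation (adjusted p = 1.75e-12 for interferon response and 9.35e-09 for cytokines and chemokines) and neither with an estimated correlation (adjusted p = 0.242 for each). Adjusted over the list alone, 14 and 11 members rose and 1 of each list fell. The means in NDMA animal 1 were 0.96 and 0.81 above the control mean, and with the slide as a block the list medians were 0.45 and 0.73.

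**Figure D2:**
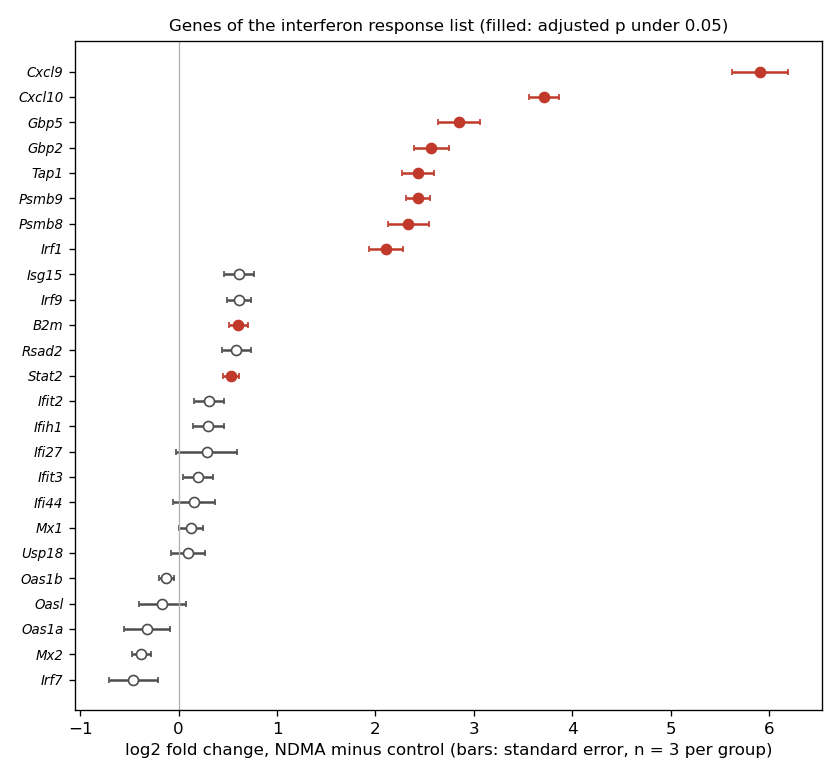
Log2 difference between NDMA and control (horizontal axis, with its standard error, 3 animals per group) for measured genes of the interferon response list, 1 of the 26 left out, ordered by size; filled red points passed an adjusted p of 0.05 and open points did not. The members shown that passed run from Stat2 at 0.53 to Cxcl9 at 5.91, and the lowest member is Irf7 at -0.46.

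Cell-cycle genes were higher after NDMA as lists, though not with an estimated correlation (adjusted p = 0.242). Of 28 measured mitosis genes 17 rose and 0 fell, with a median log2 difference of 1.30. Ccnb2, a mitotic cyclin, rose 3.02-fold (1.60 ± 0.17), Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, 3.03-fold (1.60 ± 0.20), the abscission gene Cep55 3.33-fold (1.74 ± 0.14) and the mitotic kinase Pbk 2.47-fold (1.30 ± 0.17). Kif11 was the only member below 0, at -0.34, and did not pass. Of 28 DNA replication genes 8 rose and 0 fell, with a median of 0.54. They included Ccne1, the cyclin of entry into S phase (3.22-fold, 1.69 ± 0.19), Mcm3, a subunit of the replicative helicase (3.03-fold, 1.60 ± 0.19), the helicase loader Cdc6 (2.62-fold, 1.39 ± 0.19) and the transcription factor E2f1 (1.92-fold, 0.94 ± 0.12). Pcna did not pass, at 0.28. No probe was matched by name to the proliferation marker Mki67, so it has no value here.

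The mitosis and replication lists passed with the preset correlation (adjusted p = 1.27e-23 and 4.19e-15) and not with an estimated one (adjusted p = 0.242 for each); adjusted over the list alone, 26 and 18 members rose and 1 and 0 fell. The means in NDMA animals 1 to 3 were 0.94, 1.61 and 1.04 above the control mean for mitosis and 0.52, 0.95 and 0.60 for replication. With the slide as a block the list medians were 1.01 and 0.37.

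Of 27 measured p53 targets 2 rose and 0 fell, with a median log2 difference of 0.24, and 4 and 5 rose with the normexp settings. The 2 were Plk2, a kinase (4.59-fold, 2.20 ± 0.38), and Bbc3, which encodes the pro-apoptotic protein PUMA (2.07-fold, 1.05 ± 0.14). Each of these 2 calls was kept in only 1 of the 6 fits without 1 animal. Both were lost with the slide as a block, as were most calls of named genes, those of C1qb, Cd3g and Ccnb2 among them. Mdm2, the p53 ubiquitin ligase, differed by 0.41 ± 0.13 (adjusted p = 0.181) and Apaf1 by 0.40 ± 0.08 (adjusted p = 0.0555). For Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, 3 probes of 1 transcript disagreed. The brightest, used here, differed by -0.19 ± 0.08 (adjusted p = 0.268), and the other two by 1.92 ± 0.42 and 2.26 ± 0.49 (adjusted p over probes 0.0783 and 0.0745), so no direction is given. Of 13 genes of homologous recombination and checkpoints 2 rose, among them Brca2, a mediator of the repair of double-strand breaks (1.87-fold, 0.90 ± 0.16), whereas Rad54l differed by 0.94 ± 0.19 (adjusted p = 0.0573). Mgmt, the enzyme that repairs the guanine methylation caused by nitrosamines, differed by 0.20 ± 0.14 (1.15-fold, adjusted p = 0.466), and by -0.09 with the slide as a block. Of 22 alkylation and mismatch repair genes 1 fell, Alkbh2, a dioxygenase that removes methyl groups from DNA bases (-0.44 ± 0.08, adjusted p = 0.0427). The calls of Alkbh2 and Brca2 were lost with the slide as a block (adjusted p = 0.341 and 0.317) and in each fit without 1 of the 6 animals. The repair list did not pass (adjusted p = 0.694, median 0.01). Cyp2e1, the cytochrome that oxidises NDMA, differed by 0.01 ± 0.11 (adjusted p = 0.971), and 0 of the 20 measured genes of cytochromes P450 and conjugation passed (list adjusted p = 0.135, median -0.24).

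The p53 and recombination lists passed with the preset correlation (adjusted p = 0.000120 and 0.000898) and not with an estimated one (adjusted p = 0.315 for each); adjusted over the list alone, 8 and 4 members rose and 0 fell. The means in NDMA animals 1 to 3 were 0.34, 0.61 and 0.28 above the control mean for p53 targets and 0.27, 0.62 and 0.34 for recombination. With the slide as a block the list medians were 0.22 and 0.18, against 0.24 and 0.25 without it.

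Some genes of the tubular injury list rose, but Havcr1 and Lcn2 did not pass. Of 27 measured tubular injury genes 5 rose and 0 fell, with a median log2 difference of 0.56 that was 0.30 without NDMA animal 2. They were Gpnmb, a glycoprotein of macrophages and injured epithelium (6.14-fold, 2.62 ± 0.22), the hyaluronan receptor Cd44 (2.94-fold, 1.56 ± 0.17), the protease inhibitor Timp1 (1.72-fold, 0.78 ± 0.09), the galectin Lgals3 (1.62-fold, 0.69 ± 0.11) and the intermediate filament Vim (0.70, adjusted p = 0.0315). Whole cortex was measured, so the cells that carried these transcripts are not known. Of the 4 probes of Cd44, 1 differed by -0.10 and the others by 0.82 to 1.56. Havcr1, which encodes kidney injury molecule KIM-1, differed by 1.42 ± 0.93 (adjusted p = 0.444), with a signal of -0.85 in NDMA animal 2 against -4.33 and -4.14 in the other two and from -4.91 to -3.94 in the controls. Lcn2, which encodes the injury marker NGAL, differed by 0.75 ± 0.53 (adjusted p = 0.473). Of 20 extracellular matrix and fibroblast genes 1 rose, Mmp2, a gelatinase (2.85-fold, 1.51 ± 0.26), and the median was 0.12; Tgfb1 differed by 0.53 ± 0.14, and Col1a1 and Acta2 by 0.48 and -0.16, without passing.

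Tubular injury passed with the preset correlation (adjusted p = 1.18e-07) and so did extracellular matrix (0.00777), neither with an estimated one (adjusted p = 0.242 and 0.252); adjusted over the list alone 9 and 1 members rose and 0 fell. The means in NDMA animals 1 to 3 were 0.58, 1.097 and 0.46 for injury and 0.21, 0.38 and 0.36 for matrix. With the slide as a block the list medians were 0.37 and 0.08, against 0.56 and 0.12 without it.

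Proximal tubule genes were slightly lower as a list, though not with an estimated correlation (adjusted p = 0.315). Of 36 measured members, 32 had a difference below 0, 1 fell and 0 rose, with a median log2 difference of -0.26 that was -0.15 with quantile normalisation and -0.14 with normexp and quantile. The member that fell was Lrp2, the endocytic receptor megalin (-0.57 ± 0.10, 1.48-fold, adjusted p = 0.0448), and that call was lost in several settings, among them quantile normalisation, the mean of its probes, the slide as a block (adjusted p = 0.363) and each fit without 1 of the 6 animals. The transporters Slc13a3, Slc22a6 and Slc34a1 differed by -0.39 ± 0.08, -0.37 ± 0.10 and -0.26 ± 0.08 and did not pass; with quantile normalisation these were -0.17, -0.16 and -0.06. Of 27 fatty acid oxidation genes 0 passed, and the median was -0.13. Crat and Ppara were among the members with the smallest p, at -0.45 ± 0.09 and -1.20 ± 0.23 (adjusted p = 0.0538 and 0.0542). Their other probes differed by -0.52 ± 0.10 and -1.21 ± 0.20 (adjusted p over probes 0.0485 and 0.0342). With normexp both passed (adjusted p = 0.0332 and 0.0230), and with normexp and quantile only Ppara did (0.0570 and 0.0250). Neither passed with quantile normalisation (0.0797 and 0.0569). In the other nephron segments 0 genes passed, and the medians were -0.17 over 11 loop of Henle genes, -0.02 over 9 distal tubule genes and -0.15 over 19 collecting duct genes. The collecting duct median ran from -0.20 to -0.04 without 1 animal and was -0.02 with the slide as a block. Umod, the uromodulin gene of the loop of Henle, differed by -0.21 ± 0.19 (adjusted p = 0.583), and by -0.00072 with quantile normalisation.

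Proximal tubule (adjusted p = 2.85e-05) and fatty acid oxidation (0.0197) passed with the preset correlation and not with an estimated one (adjusted p = 0.315 and 0.416), and adjusted over the list alone 2 members of each fell; the loop, distal tubule and collecting duct lists did not pass (adjusted p = 0.0641, 0.691 and 0.135). The means in NDMA animal 1 were -0.18 and -0.13 against controls between -0.17 and 0.10 and between -0.11 and 0.07. With the slide as a block the list medians were -0.19 and -0.13, against -0.26 and -0.13 without it. The oxidation list did not pass with quantile normalisation (adjusted p = 0.167) or with either normexp setting (0.119 and 0.0949). It also did not pass without control 1, control 2 or NDMA animal 2 (highest adjusted p = 0.106).

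Of 16 immediate early genes, Egr2 rose at least 3.15-fold over controls not well above background (adjusted p = 0.0291, and 0.0507 with quantile normalisation). Fos rose 1.92-fold (0.94 ± 0.15), while Klf4 differed by 0.58 ± 0.12 (adjusted p = 0.0683), and the list median was 0.31. With normexp Egr2 differed by 0.53, below that bound, and Fos by 0.49 with its call lost (adjusted p = 0.0630). The calls of Egr2 and Fos were each kept in 1 of the 6 fits without 1 animal. Of 22 endoplasmic reticulum stress genes 0 passed, although 20 had a difference above 0, and the median was 0.13, with 0.54 ± 0.11 for Sdf2l1, 0.75 ± 0.16 for Trib3 and 0.81 ± 0.28 for Atf3. Of 26 Nrf2 antioxidant genes 1 rose, Hmox1, the heme oxygenase (1.97-fold, 0.98 ± 0.16). That list did not pass (adjusted p = 0.381), and its median of -0.04 and mean of 0.10 differed in sign. Of 14 heat shock genes 0 passed (list adjusted p = 0.426, median -0.17).

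Immediate early and endoplasmic reticulum stress passed with the preset correlation (adjusted p = 0.000218 and 0.000352) and not with an estimated one (adjusted p = 0.242 and 0.315); adjusted over the list alone, 3 and 2 members rose. The means in NDMA animal 1 were 0.58 and 0.19, and the list medians with the slide as a block were 0.51 and 0.17.

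Markers of other cells that the tissue holds did not pass as lists in the planned test. The medians were 0.06 over 15 podocyte genes (adjusted p = 0.0928, and 0.0444 on ranks), 0.004 over 15 endothelial genes (0.190) and 0.06 over 9 blood genes (0.187), with 0 members past the threshold in each and differences of 0.12 for Hbb and -0.06 for Hba-a1, the haemoglobin genes. Perirenal fat had a median of 0.32 over 8 genes (adjusted p = 0.0508, 0.0495 with the slide as a random block and 0.0394 with the median of each array). That median was 0.085 with normexp and 0.16 with normexp and quantile (adjusted p = 0.0788 and 0.116), and 0.21 to 0.46 without 1 animal. The adrenal list, at a median of -0.04 over 6 genes (0.639), had a mean of 0.01, so its median and mean differed in sign. Of 10 renin angiotensin genes 1 rose, Cma1, and the list (adjusted p = 0.143, and 0.0250 over probes well above background on all arrays) had a median of -0.21 and a mean of 0.01. Cholesterol synthesis, lipogenesis and circadian clock genes had medians of -0.13, -0.14 and -0.13 over 23, 16 and 15 genes (adjusted p = 0.135, 0.111 and 0.283), with 0 members passing. Without 1 animal these medians ran from -0.17 to -0.07, from -0.17 to -0.12 and from -0.21 to -0.03. With the slide as a fixed block the cholesterol synthesis median was -0.11. All 11 male sex dependent kidney genes had a difference below 0, with a median of -0.57, but 0 passed (list adjusted p = 0.0637, 0.0444 on ranks and 0.0488 with normexp and quantile). Without control 1 that median was -0.26, and without control 3 -1.07. The controls alone differed widely over that list, with means of 0.96, 0.28 and -1.24 around their common mean.

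**Figure D3:**
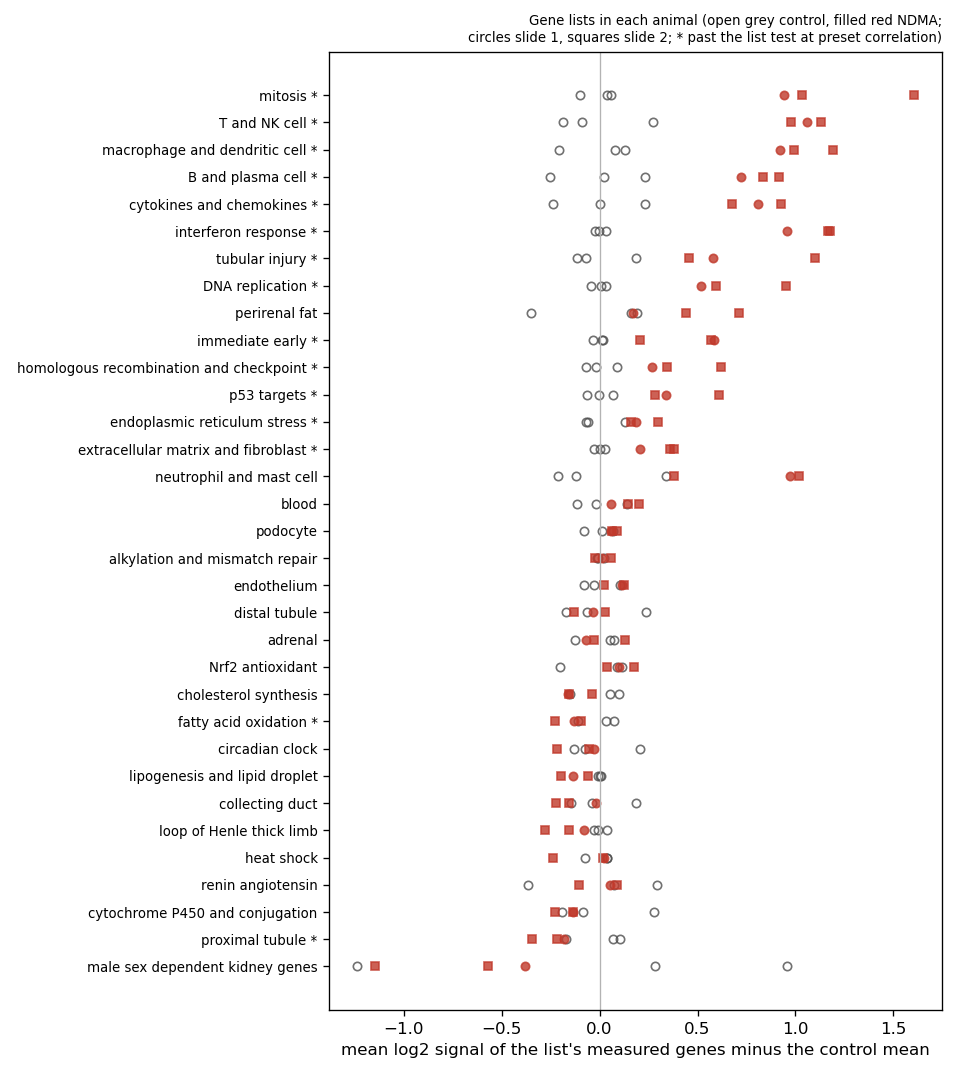
Mean log2 signal over the measured genes of each of the 33 lists in each animal, minus the mean of the 3 controls (horizontal axis), with open grey points for controls, filled red points for NDMA, circles for slide 1 and squares for slide 2; an asterisk marks the 15 lists past the list test at the preset correlation. All 3 NDMA animals lie above all 3 controls for mitosis, with 0.94 the lowest of them, and the controls are widest apart for the male sex dependent genes.

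Of the 33 lists, 15 passed with the preset correlation, 13 higher and 2 lower, and 0 with an estimated correlation. Limma's fry called 8 (adjusted p from 0.00415 to 0.0347). These were mitosis, DNA replication, tubular injury, interferon response, cytokines and chemokines, and the macrophage, T and NK cell and B and plasma cell lists. The rest of the 15 did not pass with fry (adjusted p from 0.0618 to 0.128). Of the 63 named genes past the threshold, 9 also passed with the slide as a block (Acod1, Cxcl9, Cxcl10, Cxcl11, Gpnmb, Pimreg, Psmb9, Ptx3 and Tap1), and 24 passed without any 1 of the 6 animals.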

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

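The normexp settings and the test of RefSeq-named genes alone were chosen after the data were examined, and the other alternatives before. Normexp used the median signal in place of the mean signal it was planned on, which the files used here lack. The count of 957 changed genes stayed within 1.5 times under the other settings of normalisation, background, summary and variance, including the authors' deposited values (955). It was 575 with probes well above background on at least 1 array and 371 with no filter, settings that add dim probes to the test, 627 with named genes alone, where fewer genes were tested, and 1701 at an adjusted p under 0.1. It was 67 with the slide as a fixed block and 0 on slide 1 alone, where the NDMA effect rests on 1 animal, and 1070 with the slide as a random block (correlation -0.037). Leaving out 1 animal gave 364 to 749 changed genes. With the replicate block it was 351, of which 327 were among the 957; deviations of animals with the same number correlated at 0.0386, -0.0481 and 0.0257, unlike numbers reached 0.0751, and the numbers were not taken as pairs. The 15 lists became 0 with an estimated correlation and 8 with fry. The other settings gave 14 to 20, leaving aside the fixed slide block and slide 1 alone, for which list p-values are not given. Low signal limits genes such as Ifng, Egr2 and Blk, whose controls were not well above background.

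The named genes and lists past the threshold kept their direction in every setting run. Without 1 animal the median of tubular injury ran from 0.30 to 0.67, of recombination from 0.16 to 0.30, of immediate early genes from 0.22 to 0.48, of endoplasmic reticulum stress from 0.08 to 0.21, of extracellular matrix from 0.10 to 0.19 and of fatty acid oxidation from -0.21 to -0.12. Quantile normalisation ended the calls of Dio1, Egr2, Lrp2, Mcpt1 and fatty acid oxidation. Normexp ended 8 named calls with the 75th percentile and 7 with quantile, among them Alkbh2, Blk, Cd37, Cdc6, Ddias and Mcpt1 in both, and took the medians of recombination from 0.25 to 0.07, of T and NK cells from 1.20 to 0.73, of B and plasma cells from 0.81 to 0.17, of immediate early genes from 0.31 to 0.18 and of extracellular matrix from 0.12 to 0.06 with the 75th percentile. Cma1 and Fos were also lost with normexp and the 75th percentile, and Or4p7 with normexp and quantile. Lists that had not passed but did so in at least 1 fit without 1 animal were loop of Henle, collecting duct, podocyte, cholesterol synthesis, lipogenesis, renin angiotensin, neutrophil and mast cell, male sex dependent and perirenal fat. Results that turned direction had not passed, and the cause was not tested except for Cdkn1a, whose probes disagree: it was 1.33 with the mean of its probes (adjusted p = 0.0879). Mgmt was -0.0929 with the slide as a block and on slide 1 alone. Cyp2e1 was -0.0089 with the median of each array and -0.0534 to 0.0958 without 1 animal. Among list medians, Nrf2 antioxidant was 0.0304 with quantile normalisation, 0.0371 with normexp and quantile, 0.0381 with the slide as a block and on slide 1 alone, and -0.112 to 0.0454 without 1 animal. Distal tubule was 0.0355 with quantile normalisation and -0.118 to 0.0918 without 1 animal. Alkylation and mismatch repair was -0.0090 with the median of each array, -0.0103 with normexp, -0.0011 with the slide as a block and on slide 1 alone, and -0.0115 to 0.0266 without 1 animal. Endothelium was -0.0148 with the median of each array and -0.0072 to 0.11 without 1 animal. With normexp, podocyte was -0.00031 and blood -0.0308. Adrenal was 0.14 with probes well above background on at least 1 array, 0.24 with no filter and -0.0945 to 0.0435 without 1 animal.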

Other observations

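The gene families described here and all the tests of explanations were chosen after the results were seen. Genes of antigen presentation rose, most of them outside the fixed lists. Of 35 measured genes of the rat major histocompatibility complex (RT1 genes), 20 rose and 0 fell, with a median log2 difference of 0.99. Of all 12175 features with a RefSeq gene name, 427 rose. No p-value is given for the families, because they were picked from the same calls that such a test would count. Class I genes such as RT1-A2 (3.00-fold, 1.58 ± 0.19) and RT1-A1 (1.85-fold, 0.89 ± 0.09) and class II genes such as RT1-Bb (2.60-fold, 1.38 ± 0.24) and RT1-Da (2.41-fold, 1.27 ± 0.13) were among them, and Ciita, the transactivator of class II genes, rose 2.37-fold. Of 43 proteasome subunits 5 rose, and these were the immunoproteasome subunits Psmb8, Psmb9 and Psmb10 and the activator subunits Psme1 and Psme2, while the median over all 43 was 0.01 (-0.01 with the median of each array). Of 7 measured GTPases of cell-autonomous immunity 6 rose, among them Irgm (4.23-fold) and Ifi47 (4.27-fold). Psmb8, Psmb9, Gbp2 and Gbp5, counted here, are also members of the interferon response list. In NDMA animal 1, on the controls' slide, the means over the RT1 genes and over the GTPases were 0.96 and 1.74 above the controls. These families hold near-identical members, and hybridisation across members would add to their counts.

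Receptors of innate immunity rose in part. Of 20 killer-cell lectin receptors 7 rose, including Klri1 (2.46-fold, 1.30 ± 0.16) and Klra2 (2.86-fold, 1.52 ± 0.26), and of 11 toll-like receptors Tlr1, Tlr6, Tlr10 and Tlr11 rose. The medians over these families were 0.56 and 0.57, and with the normexp settings 0.12 and 0.20 for the lectin receptors and 0.31 and 0.36 for the toll-like receptors, with 5 and 3 members rising in the first of them. Of 12 cathepsins Ctse, Ctss, Ctsw and Ctsz rose, Ctse 2.99-fold (1.58 ± 0.12), while the median over the family was -0.05 and 5 members were above 0. Of 280 solute carriers 6 fell and 0 rose (2 and 3 rose with the normexp settings). Those that fell included the monocarboxylate transporters Slc16a11 and Slc16a13, at -0.49 ± 0.09 and -0.47 ± 0.08. The share that fell was 2.14%, against 0.476% of all named genes. Of 74 ribosomal protein genes 0 passed.

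The immune-cell and interferon lists, 67 measured genes of which 37 rose, were higher by 1.07 on average. If slide or scan day alone had raised them, NDMA animal 1 would have stayed among the controls of its slide, but its mean over these genes was 0.98 above theirs, whose range was 0.25, and the slide 2 animals were at 1.11 on average. A smaller share of tubule cells would raise podocyte and endothelial genes as much as immune-cell genes, and their mean shift was 0.0788 against 1.05. Blood left in the tissue would raise erythroid and platelet genes, whose mean shift, without Slc4a1, which the collecting duct also expresses, was 0.15. More leukocytes, more transcript per leukocyte and induction of interferon genes in resident kidney cells were not tested and stay open.

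Within the interferon list, 14 members that were classed as type I interferon genes after their values had been seen had a mean shift of 0.0867, with 0 rising, and the other 12 had 2.28, with 11 rising (12 with the normexp settings). The standard error of the difference between animals was 0.16. Because the members were sorted on the values they were then compared by, and Stat2 and Irf9, which also carry type I signals, were placed among the others, the difference is no test of which interferon acted, and that is left open.

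Mitosis and replication genes, 56 measured and 25 risen, were 0.73 above the controls in NDMA animal 1, and the controls' range was 0.11, which argues against slide or scan day as the whole source. Immune cells that divide at an unchanged rate would raise mitosis genes by no more than immune-cell genes. The mitosis members rose by 0.15 more, with a standard error of 0.25, so it stays open whether the dividing cells may be leukocytes, tubule cells or both. NDMA animal 2 had the highest mean for mitosis (1.61), p53 targets (0.61) and tubular injury (1.097) and the highest Havcr1, and 1 animal does not show a relation between them.

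The proximal tubule list was lower by 0.25 on average. NDMA animal 1 was at -0.18, against -0.17 for the lowest control, and the slide 2 animals at -0.28 on average, so a slide effect cannot be told apart from NDMA for this list. Dilution by added cells could lower all tubule segments alike, and the mean shift of loop, distal tubule and collecting duct genes was -0.12, with a standard error of 0.17 for its difference from the proximal genes, which leaves dilution open beside a loss of proximal tubule expression.

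Of the 10 ways to split the 6 animals 3 against 3, 1, the real one, gave as many changed genes (957, against at most 4). For lists it was also 1, with 15 against 3 to 13 in the other splits, so mixed groups called lists too. With 10 splits the share cannot fall under 0.1, which is too few to reach 0.05.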
